A study of Drosophila melanogaster with 9 samples.

How the data were processed

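RNA-Seq was done on heads of adult Drosophila melanogaster females, 1 to 2 days old, kept at 25 °C and 60% humidity, in 9 libraries of 3 groups (control, Ime4 heterozygous and Ime4 homozygous, 3 libraries each). Per the labels' protocols, RNA was extracted with Trizol, poly(A) RNA was selected on oligo-dT beads and libraries were made with a directional kit. Per the submitters' processing notes, base calls came from CASAVA 1.8.4, reads were aligned to BDGP6 with STAR 2.4.0h and counted in genes with HTSeq 0.6.1, and DESeq2 1.6.3 was used for their own tests. The authors deposited read counts per gene, 1 column of counts per library, with 17558 gene rows and 5 lines for reads not counted in a gene. The strand setting of the counting is not given in the notes, so reads of overlapping and antisense genes may be shared between partners. Reads without a unique position were kept out of the gene counts and listed on a line of their own.

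Gene IDs were matched to an Ensembl annotation of the same assembly, which held 17252 of the 17558 IDs, and coordinates are from that annotation. Ime4 is listed there as Mettl3 and YT521-B as Ythdc1. Depth was 2730289 to 4272550 reads in genes per library. Counts were scaled with TMM factors between 0.9583 and 1.075 in edgeR 4.0.16 (R 4.3.3), and genes were kept with filterByExpr (minimum count 10, minimum total 15), which left 8972 genes. Differences were tested with edgeR's quasi-likelihood test on the 3 group means, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. The edgeR adjusted p in the results is from that test. Log2 CPM for the principal components used a prior count of 2.

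A total of 37 gene lists held 1510 distinct genes, and lists with at least 3 tested members were tested with camera in limma 3.58.1 with a preset correlation of 0.01, with camera with an estimated correlation, and with fry. Camera compares the members of a list with all other tested genes, and its p-values were adjusted over the 33 lists tested. Lists of ovary markers and mitochondrially encoded transcripts had 0 tested members, and lists of testis markers and of small nucleolar and spliceosomal RNAs had 1 each, so they were not tested. Calls in the preset setting numbered 12 in homozygous against control, 12 in heterozygous against control and 7 in homozygous against heterozygous flies. With an estimated correlation camera called 0, 0 and 0, and fry, which does not compare a list with other genes, called 14, 9 and 4.

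The genes named were set by rule: Ime4, the members of the m6A list and of the sex determination list, and the strongest changes per comparison. The last were the 10 highest and 10 lowest fold changes for homozygous against control and the 8 highest and 8 lowest for the others, among called genes with a mean of at least 2 CPM and no overlap between the libraries compared. Up to 4 members of every other list with the lowest p and the 10 strongest genes called the same way in homozygous flies against both groups were added. The rule sets which genes may be named, and the text names part of them. This rule, the lists, the comparisons and most alternatives were chosen before the data were examined. For genes with 0 reads in a group, fold changes were computed against a floor of 3 reads over the group, and with 1 to 3 reads a ratio with a 95% counting interval was given. Intervals and floors cover counting error only.

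X-linked against autosomal levels were compared per library with exact permutation tests, and calls near Ime4 with Fisher's exact test in windows of 2, 0.5 and 5 Mb on each side. Alternatives were other size factors, no filter or at least 10 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a fold change of at least 2, an adjusted p threshold of 0.01, only the 2 groups compared, the replicate number as a block, and leaving out each of the 9 libraries. Fits without the libraries that held transcripts of other tissues, and with libraries corrected for exon length, were chosen after seeing the data. The replicate numbers did not pair the libraries: correlations of deviations from the group means lay between -0.0659 and 0.117 for libraries with the same number and between -0.114 and 0.114 for the others.

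The steps were tested on simulated data drawn from the libraries' own means. Over 10 draws with 200 changed genes each, in the homozygous against control setting, edgeR recovered on average 18.5% of genes changed 1.5-fold, 64.9% at 2-fold and 92.9% at 4-fold, and between 3.15% and 12.1% of its calls (mean 7.45%) were unchanged genes. In the homozygous against heterozygous setting the averages were 20.6%, 66.1% and 94.1%, with between 1.69% and 9.16% of calls (mean 6.19%) on unchanged genes. The share of false calls was thus above the threshold of 0.05 in the mean of both settings. Of 30 simulated lists without a shift camera called 0. Genes in these lists were drawn independently of each other, so the calls on lists with correlated members were not checked by it. The estimated correlation was 0.67 between members of the ribosomal list and 0.826 between those of the digestive enzyme list. Splicing and m6A itself were not analysed here.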

Results

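Poly(A)-selected RNA from the heads of adult Drosophila melanogaster females, 1 to 2 days old, was sequenced in 9 libraries. The libraries formed 3 groups of 3: control flies, flies heterozygous for Ime4 and flies homozygous for Ime4. Ime4 encodes the catalytic subunit of the complex that methylates adenosines in messenger RNA (m6A), and YT521-B is the nuclear protein that binds the modified base. The series names neurogenesis and sex determination as the processes under study. Reads counted in genes ranged from 2730289 to 4272550 per library, with group means of 3120540 ± 363400 in control, 3562920 ± 133380 in heterozygous and 3977240 ± 338908 in homozygous flies (SD, n = 3). Of 17558 genes listed, 3991 had no read in any library and 8972 had enough reads to be tested. Values per gene are given as read counts scaled to library size (CPM) after TMM scaling, mean ± SD over the 3 libraries of a group, and log2 fold changes with their standard error (SE). Nothing in the labels says that the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries.

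The 3 groups separated from each other across the transcriptome. The first principal component held 37.4% of the variance and placed control libraries between -33.2 and -25.8, heterozygous libraries between 2.08 and 6.97 and homozygous libraries between 15.4 and 32.2. The second held 19.5% and set the heterozygous libraries, between -24.3 and -22.0, apart from all others, between 2.54 and 16.0. The third held 12.7% and set homozygous replicate 3, at -34.8, apart from every other library.

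**Figure D1:**
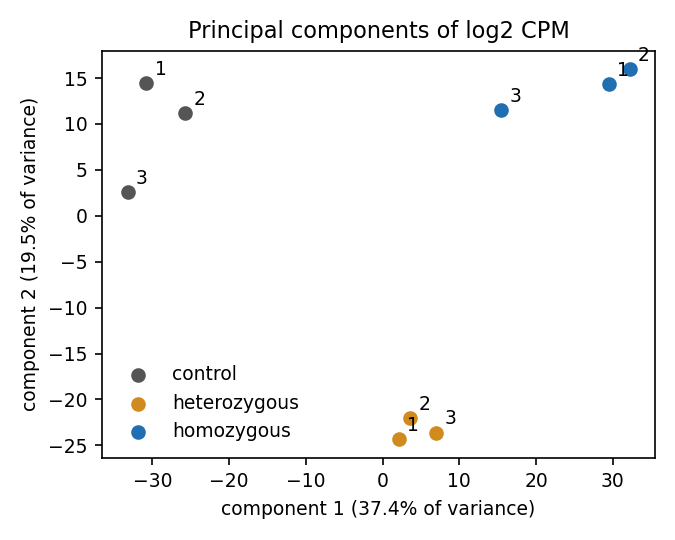
Principal components 1 and 2 of log2 CPM, with the percentage of variance on each axis. Each point is a library with its replicate number, coloured by group; control, heterozygous and homozygous libraries lie in separate parts of the plot.

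Transcripts of other tissues appeared in single libraries. The ovary list (20 genes, among them eggshell protein genes) held 415 RPM (reads scaled to library size) in control replicate 3 and between 1.68 and 8.23 in the other 8 libraries. In that library the vitelline membrane genes Vm26Aa and Vm34Ca had 319 and 290 reads and dec had 325, genes chosen after their values were seen. The digestive enzyme list (44 genes) held 978 and 1119 RPM in homozygous replicates 1 and 2, 70.8 in homozygous replicate 3 and between 22.3 and 92.5 in the 6 control and heterozygous libraries. Reads outside annotated genes made up 29.4 ± 2.83% of the counted total in control, 23.6 ± 4.68% in heterozygous and 19.1 ± 1.62% in homozygous libraries (SD, n = 3). Reads without a unique position made up 15.5 ± 0.438%, 12.5 ± 1.77% and 10.2 ± 1.82%.

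**Figure D2:**
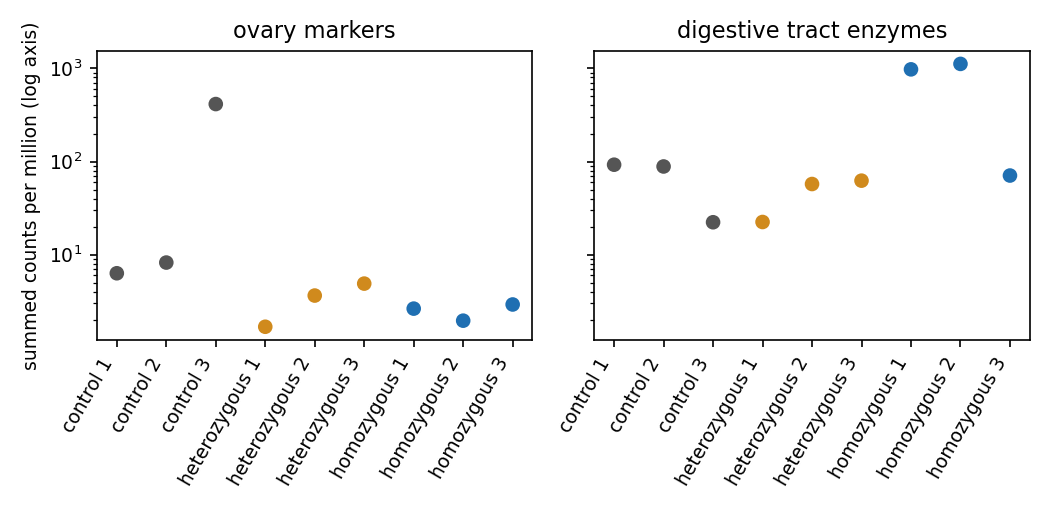
RPM summed over the ovary list (left) and the digestive enzyme list (right) in each of the 9 libraries, on a log axis. Control replicate 3 stands at 415 for ovary transcripts, and homozygous replicates 1 and 2 stand at 978 and 1119 for digestive enzymes.

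The targeted gene was lowest in the homozygous libraries. Ime4, listed as Mettl3 (FBgn0039139, 3R 24032157 to 24034257), had 17, 19 and 18 reads in control, 8, 13 and 16 in heterozygous and 3, 3 and 2 in homozygous libraries. These were 5.66 ± 0.568, 3.59 ± 1.32 and 0.681 ± 0.179 CPM (SD, n = 3). Mettl3 fell in homozygous against control flies by 3.00 ± 0.45 on the log2 scale (SE; edgeR adjusted p = 5.56e-04) and against heterozygous flies by 2.34 ± 0.48 (edgeR adjusted p = 0.0116). The second call was lost without heterozygous replicate 2 or 3, at -2.33 and -2.09 with edgeR adjusted p = 0.0584 and 0.065. Heterozygous against control flies, at -0.65 ± 0.35, did not pass the test (edgeR adjusted p = 0.285). Which part of the gene the allele removes is not given in the labels, so the remaining reads could not be placed inside or outside it.

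YT521-B, listed as Ythdc1 (FBgn0027616, 3L 3370451 to 3374170), also fell in homozygous flies, from 134 ± 12.4 CPM in control to 61.1 ± 4.08 (SD, n = 3; log2 fold change -1.14 ± 0.12, edgeR adjusted p = 3.74e-05). In heterozygous flies it stood at 98.7 ± 8.69 CPM, and the fold changes were -0.44 ± 0.12 for heterozygous against control (edgeR adjusted p = 0.0347) and -0.69 ± 0.12 for homozygous against heterozygous (edgeR adjusted p = 0.00615). The heterozygous call was lost without any one control or heterozygous library, at -0.49 to -0.36 with edgeR adjusted p up to 0.174. Of the 9 m6A genes tested, Mettl3 and Ythdc1 were called in homozygous against control flies, and also when adjusted over the list alone. The writer subunits Mettl14 (0.27 ± 0.26), fl(2)d (0.16 ± 0.11), vir (0.60 ± 0.28), nito (-0.25 ± 0.14), Flacc (0.02 ± 0.12) and Hakai (0.07 ± 0.47) and the cytoplasmic reader Ythdf (-0.04 ± 0.13) did not pass.

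**Figure D3:**
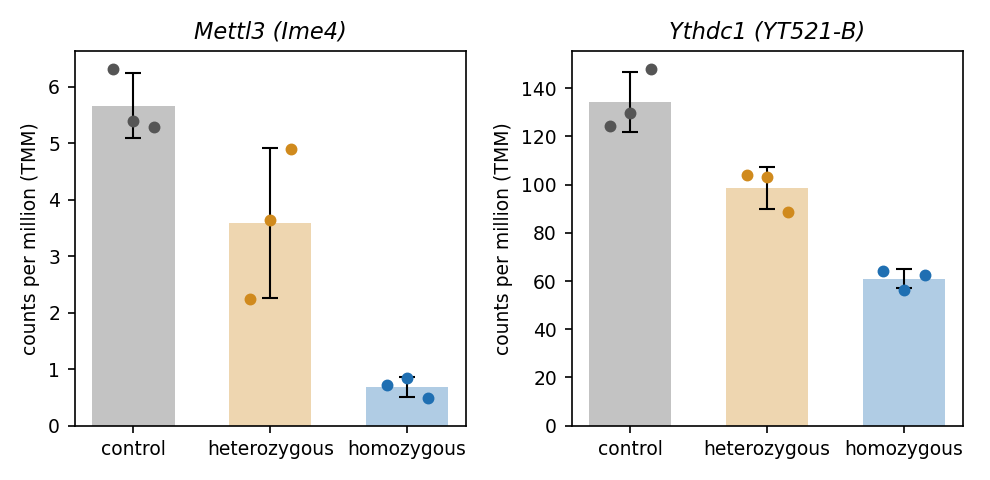
CPM of Mettl3 (Ime4, left) and Ythdc1 (YT521-B, right) in control, heterozygous and homozygous heads. Bars are means, whiskers SD and points the 3 libraries of a group; mean Mettl3 CPM is 5.66, 3.59 and 0.681 and mean Ythdc1 CPM 134, 98.7 and 61.1.

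Homozygous flies were compared with control flies to find the transcripts that differ in adult heads of Ime4 mutants. Several single transcripts were nearly lost. Ugt35B1, a UDP-glycosyltransferase gene (FBgn0026314, 3R 11168503 to 11170246), fell from 84.4 ± 2.86 to 2.4 ± 0.947 CPM (SD, n = 3; log2 fold change -5.14 ± 0.20, edgeR adjusted p = 1.64e-09). CG31808 (FBgn0062978, 2L 16704286 to 16716195) fell from 340 ± 21.7 to 9.94 ± 0.315 CPM (-5.09 ± 0.13, edgeR adjusted p = 1.38e-11). sordd2 (FBgn0052581, X 15796908 to 15799162) had 317 reads over the control and 0 over the homozygous libraries, at least 130-fold lower with a floor of 3 reads over the group. CG8245 (FBgn0033031, 2R 5668383 to 5669986) had 322 and 1 reads, a ratio of 397 with a 95% counting interval of 70.7 to 15700.

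Among the highest fold changes of the same comparison, Drsl4, a drosomycin-like peptide gene (FBgn0052282, 3L 3315620 to 3315942), rose from 2.62 ± 1.02 to 90.0 ± 7.01 CPM (SD, n = 3; 5.09 ± 0.24, edgeR adjusted p = 1.21e-08). The rise was 5.30 ± 0.34 for CG34215, 4.66 ± 0.48 for yellow-d2 and 4.45 ± 0.44 for the cytochrome P450 gene Cyp4p2 (edgeR adjusted p = 4.17e-07, 2.33e-05 and 1.76e-05). Ir76a, an ionotropic receptor gene, Osi2 and the zinc transporter gene ZnT33D fell by 4.58 ± 0.45, 4.33 ± 0.58 and 4.16 ± 0.61 (edgeR adjusted p = 1.66e-05, 2.24e-04 and 4.46e-04). Single libraries set the size of some of these: without control replicate 2 the values were 7.45 for yellow-d2 and 6.37 for Cyp4p2, and without homozygous replicate 3 Osi2 stood at -4.96. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 1765 of 8972 genes were called, 978 higher and 787 lower in homozygous flies, of which 367 and 168 differed at least 2-fold. The libraries of the groups did not overlap for 3027 genes, 33.7% of those tested, where chance gives 10%. The count stood at 1130 without control replicate 2, and 1070 of these were called the same way in the full fit. Without homozygous replicates 1 and 2, the libraries with digestive transcripts, many of the 1765 calls were lost and others were gained. That fit kept 1 homozygous library.

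Transcripts of the cytosolic ribosome were higher in homozygous than in control heads. Of 75 ribosomal protein genes tested 63 rose and 0 fell (68 adjusted over the list alone), with a median log2 fold change of 0.65 (camera adjusted p = 3.28e-19). It had adjusted p = 0.428 with an estimated correlation, which was 0.67 between members. Correction for exon length moved its median from 0.64 to 0.40 and kept the call (camera adjusted p = 8.52e-13). RpS27 rose from 180 ± 18.5 to 387 ± 67.0 CPM (SD, n = 3; 1.10 ± 0.15, edgeR adjusted p = 2.4e-04). Nuclear-encoded respiratory chain genes rose in 14 cases and fell in 1 of 64 (19 and 2 adjusted over the list alone), with a median of 0.36 (camera adjusted p = 4.44e-04; adjusted p = 0.775 with an estimated correlation). ATPsynD, a subunit of ATP synthase, rose by 0.71 ± 0.12 (edgeR adjusted p = 0.00154). Of 32 proteasome genes 6 fell and 0 rose (7 adjusted over the list alone; median -0.37, camera adjusted p = 7.39e-04; adjusted p = 0.71 with an estimated correlation). Rpn1, a subunit of the regulatory particle, fell by 1.03 ± 0.15 (edgeR adjusted p = 5.33e-04). Without homozygous replicates 1 and 2 the respiratory chain and proteasome lists lost their calls and turned direction (camera adjusted p = 0.804 and 0.882), and the ribosomal list kept its own (1.67e-06). The respiratory chain call was also lost without homozygous replicate 2 alone (camera adjusted p = 0.209) and after correction for exon length (0.36), where its median was 0.09 and 0.33 before.

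Transcripts of neuronal signalling were lower in homozygous than in control heads. Of 24 genes of the synaptic vesicle cycle and active zone 7 fell and 0 rose (9 adjusted over the list alone; median -0.28, camera adjusted p = 9.87e-05). Of 17 voltage-gated ion channel genes 5 fell and 0 rose (5 adjusted over the list alone; median -0.27, camera adjusted p = 4.44e-04). Both lists had adjusted p = 0.428 with an estimated correlation. The calcium sensor of vesicle release Syt1 fell from 2244 ± 180 to 1108 ± 66.8 CPM (SD, n = 3; -1.02 ± 0.11, edgeR adjusted p = 5.38e-05), Syn by 0.68 ± 0.12 and unc-13 by 0.67 ± 0.13 (edgeR adjusted p = 0.00166 and 0.00247). The potassium channel gene Shab fell by 0.87 ± 0.11 and the calcium channel genes Ca-alpha1D and Ca-alpha1T by 0.90 ± 0.11 and 0.90 ± 0.12 (edgeR adjusted p = 1.27e-04, 1.33e-04 and 2.15e-04). Of 21 genes of neurotransmitter synthesis and transport 4 fell and 0 rose, also when adjusted over the list alone (median -0.21, camera adjusted p = 0.00344; adjusted p = 0.428 with an estimated correlation). Vmat, the vesicular monoamine transporter, fell by 0.67 ± 0.12 (edgeR adjusted p = 0.00204). Without homozygous replicates 1 and 2 the transmitter list lost its call (camera adjusted p = 0.348), while the synaptic and channel lists stood at 0.0255 and 0.0107. Correction for exon length ended the channel call (median -0.16, camera adjusted p = 0.101) and moved the synaptic median from -0.28 to -0.13 (0.0117).

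Peptide hormones, learning genes and early neuronal genes moved in both directions. Of 32 neuropeptide genes 3 rose and 7 fell in homozygous against control heads (4 and 9 adjusted over the list alone; median -0.28, camera adjusted p = 0.0401; adjusted p = 0.428 with an estimated correlation). CCHa2, a nutrient-responsive peptide hormone, rose from 39.3 ± 2.63 to 83.5 ± 6.25 CPM (SD, n = 3; 1.09 ± 0.13, edgeR adjusted p = 7.45e-05), and the allatostatin B gene Mip fell by 1.21 ± 0.23 (edgeR adjusted p = 0.00251). The list's call was lost without control replicate 2 or homozygous replicate 1 or 3 (camera adjusted p = 0.0818, 0.0613 and 0.0848). Of 17 mushroom body and learning genes 1 rose and 4 fell (1 and 7 adjusted over the list alone; median -0.29, camera adjusted p = 0.0256; adjusted p = 0.633 with an estimated correlation), a call lost without control replicate 1 or homozygous replicate 2 (0.125 and 0.102) or with correction for exon length (median -0.08, camera adjusted p = 0.351). orb2, a translational regulator needed for long-term memory, fell by 0.68 ± 0.15 (edgeR adjusted p = 0.00615). Of 18 genes of neurogenesis and the Notch pathway 2 rose and 4 fell (2 and 5 adjusted over the list alone), and the list was not called (median -0.19, camera adjusted p = 0.351). elav and Rbp9, both neuronal RNA-binding proteins, fell by 0.83 ± 0.16 and 0.59 ± 0.12 (edgeR adjusted p = 0.00328 and 0.00506). In heterozygous against control heads 4 genes of this list fell and 0 rose (5 and 1 adjusted over the list alone; median -0.21, camera adjusted p = 0.098). There elav fell by 0.66 ± 0.16 (edgeR adjusted p = 0.022), a call lost without control replicate 1 or any heterozygous library, at -0.69 to -0.48 with edgeR adjusted p up to 0.108.

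Fat body and immune transcripts were higher in homozygous than in control heads. Of 17 fat body genes 10 rose and 0 fell, also when adjusted over the list alone (median 0.66, camera adjusted p = 9.87e-05). Of 27 antimicrobial and humoral immune genes 12 rose and 2 fell (15 and 2 adjusted over the list alone; median 1.00, camera adjusted p = 3.26e-04). Both had adjusted p = 0.428 with an estimated correlation. Sodh1, a sorbitol dehydrogenase, rose from 28.1 ± 3.49 to 123 ± 24.4 CPM and ACC, acetyl-CoA carboxylase, from 250 ± 24.0 to 394 ± 34.4 (SD, n = 3; edgeR adjusted p = 2.4e-06 and 0.00163). The Toll-dependent peptide gene BomS2 rose from 74.7 ± 20.8 to 847 ± 134 CPM and the recognition protein gene PGRP-SB1 from 3.00 ± 1.31 to 22.5 ± 4.6 (SD, n = 3; edgeR adjusted p = 2.30e-06 and 2.63e-05). TotA, a humoral stress peptide, rose by 2.61 ± 0.32 (edgeR adjusted p = 1.07e-04), one of 3 risen among 6 genes of a Turandot and JAK-STAT list that was not called (4 up and 1 down adjusted over the list alone; camera adjusted p = 0.0885). Without homozygous replicates 1 and 2 the fat body list stood at 3.25e-04 and the immune list lost its call (camera adjusted p = 0.106).

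All 10 digestive enzyme genes tested rose in homozygous against control heads, also when adjusted over the list alone (median 3.21, camera adjusted p = 0.0012; adjusted p = 0.61 with an estimated correlation). The reads came from homozygous replicates 1 and 2. The trypsin gene betaTry had 577, 645 and 6 reads in the 3 homozygous libraries and alphaTry 272, 280 and 11, against 4 to 11 and 0 to 10 in the other 6. Without those libraries the list was not called (camera adjusted p = 0.857), and without control replicate 3 as well its direction turned (0.445). Of 31 cuticular protein genes 10 rose and 2 fell (13 and 2 adjusted over the list alone; median 0.57, camera adjusted p = 0.0238; adjusted p = 0.428 with an estimated correlation), a call lost without control replicate 1 or homozygous replicate 3 (0.127 and 0.11) or with correction for exon length (median 0.27, camera adjusted p = 0.15). Cpr49Ae rose by 1.43 ± 0.12 and Cpr11B fell by 1.52 ± 0.17 (edgeR adjusted p = 4.21e-06 and 5.60e-05).

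Xenobiotic, light-sensing and clock genes changed in both directions, and none of these lists was called in homozygous against control heads. Of 67 cytochrome P450 genes 12 rose and 9 fell (14 and 11 adjusted over the list alone; camera adjusted p = 0.857). Cyp6w1 fell from 115 ± 7.26 to 19.9 ± 2.80 CPM and Cyp313a1 from 268 ± 21.1 to 88.2 ± 13.5, while Cyp6a20 rose from 39.8 ± 7.79 to 126 ± 24.5 (SD, n = 3; edgeR adjusted p = 7.20e-08, 3.26e-06 and 2.81e-05). Of 18 UDP-glycosyltransferase genes 2 rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.785). Of 32 phototransduction genes 3 rose and 7 fell (4 and 8 adjusted over the list alone; camera adjusted p = 0.314). Calmodulin (Cam) rose by 1.10 ± 0.12 and the blue-light opsin Rh5 by 1.02 ± 0.15, and Arr2, an arrestin, fell by 0.76 ± 0.15 (edgeR adjusted p = 5.39e-05, 5.50e-04 and 0.00326). Of 16 circadian clock genes 6 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.0596), among them tim, which rose from 127 ± 12.5 to 249 ± 41.8 CPM (SD, n = 3; edgeR adjusted p = 3.53e-04).

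**Figure D4:**
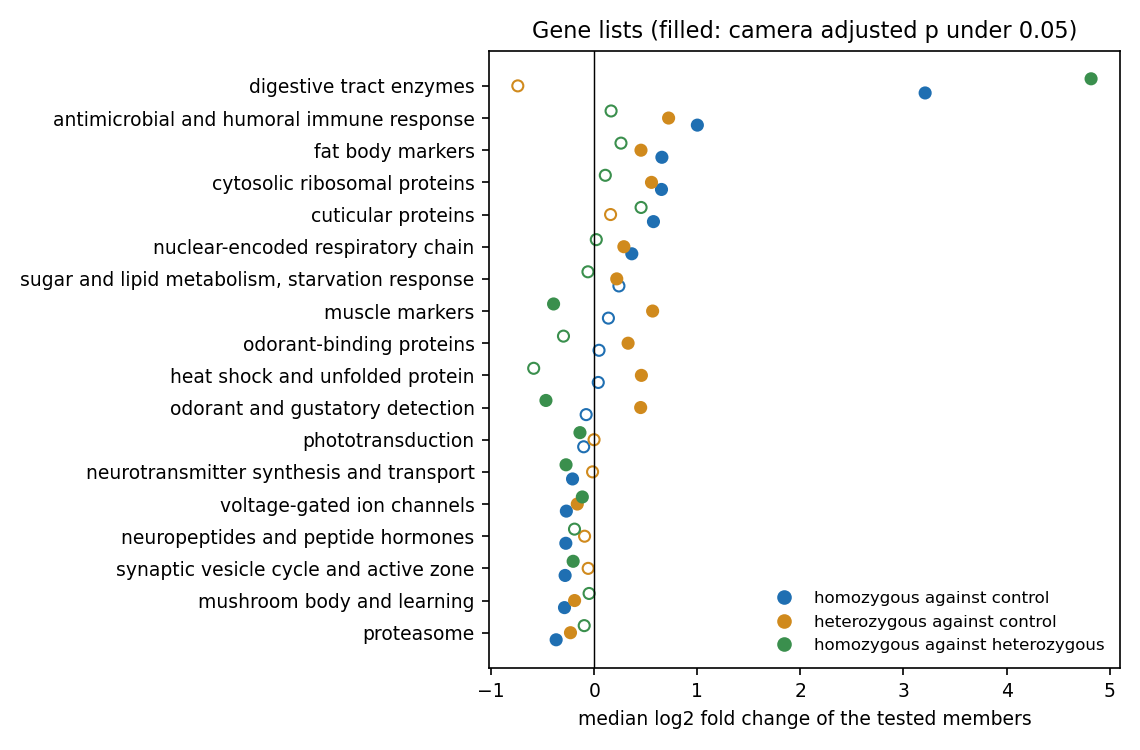
Median log2 fold change of the tested members of each gene list called in at least 1 of the 3 comparisons, with the comparisons in colour. Filled points passed camera with a preset correlation; no list passed with an estimated correlation, and the ribosomal list lies at 0.65 for homozygous and 0.56 for heterozygous against control.

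The sex determination and dosage compensation list was followed because the series title names sex determination. In each comparison at most 2 of its 16 tested genes differed at the level of whole genes, the unit in which reads were counted, and splicing was not analysed here. In homozygous against control heads 2 fell and 0 rose (1 adjusted over the list alone), and the list was not called (median -0.10, camera adjusted p = 0.395). msl-2, the male-specific dosage compensation gene that Sxl represses in females, fell from 50 ± 1.03 to 32.6 ± 2.65 CPM (SD, n = 3; -0.61 ± 0.14, edgeR adjusted p = 0.00688), and stood at -0.56 without homozygous replicates 1 and 2, where it did not pass (edgeR adjusted p = 0.0637). In heterozygous against control heads 1 gene of the list rose and msl-2 fell (-0.47 ± 0.14, edgeR adjusted p = 0.0474), a call lost in 7 of 9 fits without 1 library, at -0.56 to -0.38 with edgeR adjusted p up to 0.197. In homozygous against heterozygous flies 1 gene fell and 0 rose. The other gene of the list that fell in homozygous against control heads was her, by 0.60 ± 0.19 (edgeR adjusted p = 0.045). That call was lost without any control or homozygous library or heterozygous replicate 2, at -0.70 to -0.47 with edgeR adjusted p up to 0.13. The switch gene Sxl stood at 975 ± 134 CPM in control, 1086 ± 85.6 in heterozygous and 1216 ± 133 in homozygous flies (SD, n = 3; edgeR adjusted p = 0.11 for homozygous against control). Its downstream genes tra (0.15 ± 0.17), dsx (0.10 ± 0.17) and fru (-0.31 ± 0.13) did not pass the test. The dosage compensation RNA gene lncRNA:roX1 varied widely within the heterozygous group, with 102, 11 and 94 reads. It had 38, 41 and 23 reads in control and 16, 12 and 10 in homozygous libraries, and the cause was not tested.

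X-linked transcripts as a whole did not differ detectably between the groups. Per library, the median of the 1491 X-linked genes minus that of the autosomal genes, on centred log2 CPM, was 0.0214 ± 0.0309 in control, -0.0233 ± 0.0422 in heterozygous and 0.00376 ± 0.0312 in homozygous flies (SD, n = 3). The differences were -0.0177 for homozygous against control, -0.0448 for heterozygous against control and 0.0271 for homozygous against heterozygous (two-sided exact permutation p = 0.5, 0.3 and 0.4). With 3 against 3 libraries the smallest p possible is 0.1. Genes on the X chromosome were called in homozygous against control flies in 19.9% of cases and other genes in 19.7% (Fisher's exact test, odds ratio 1.01, p = 0.858).

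Heterozygous flies were compared with control flies as the second contrast named in the labels. The strongest differences again lay in single genes. CG31287 (FBgn0051287, 3R 16203371 to 16204961) had 118, 122 and 95 reads in the heterozygous libraries and 2 over the control libraries, a ratio of 155 with a 95% counting interval of 42.5 to 1280. In homozygous flies it stood at 0.751 ± 0.405 CPM (SD, n = 3). sordd2 and CG8245 were lower in heterozygous than in control flies by ratios of 171 (47.1 to 1420) and 348 (62.1 to 13800). CG31808 fell by 4.94 ± 0.13, and Drsl4 and Cyp4p2 rose by 4.53 ± 0.24 and 4.59 ± 0.44 (edgeR adjusted p = 2.05e-11, 1.19e-07 and 2.74e-05). Without control replicate 2 the value of Cyp4p2 was 6.51. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 836 genes were called, 498 higher and 338 lower, of which 176 and 129 differed at least 2-fold. The libraries did not overlap for 2844 genes, 31.7% against 10% by chance. Without control replicates 1, 2 and 3 in turn the count was 516, 423 and 532, without heterozygous replicates 1, 2 and 3 it was 395, 446 and 362, and without homozygous replicate 3 it was 1442. With only the control and heterozygous libraries in the fit it was 1370, and 1361 without homozygous replicates 1 and 2.

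Ribosomal, muscle, immune and fat body transcripts were higher in heterozygous than in control heads. Of 75 ribosomal protein genes 48 rose and 0 fell (65 adjusted over the list alone; median 0.56, camera adjusted p = 3.83e-22), and of 64 respiratory chain genes 5 rose and 0 fell (4 adjusted over the list alone; median 0.29, camera adjusted p = 3.10e-06). Both had adjusted p = 0.609 with an estimated correlation. Of 25 muscle genes 12 rose and 1 fell (15 and 1 adjusted over the list alone; median 0.57, camera adjusted p = 3.10e-06; adjusted p = 0.473 with an estimated correlation). The myosin light chain Mlc1 rose from 1677 ± 94.0 to 3815 ± 31.9 CPM, the myosin heavy chain Mhc from 4606 ± 490 to 7772 ± 288 and the actin Act79B from 330 ± 122 to 1146 ± 141 (SD, n = 3; edgeR adjusted p = 3.45e-04, 0.00404 and 0.00257). Of 27 immune genes 9 rose and 1 fell (14 and 1 adjusted over the list alone; median 0.72, camera adjusted p = 2.54e-05; adjusted p = 0.473 with an estimated correlation), with BomS2 at 2.85 ± 0.27 and the drosocin gene Dro at -2.65 ± 0.48 (edgeR adjusted p = 2.36e-05 and 0.00396). Dro stood at -3.27 without heterozygous replicate 2. Of 17 fat body genes 7 rose and 1 fell (10 and 2 adjusted over the list alone; median 0.45, camera adjusted p = 0.00295; adjusted p = 0.473 with an estimated correlation). AkhR, the adipokinetic hormone receptor, rose by 1.10 ± 0.18 and the larval serum protein gene Lsp1beta fell by 2.06 ± 0.39 (edgeR adjusted p = 0.0019 and 0.00525).

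Part of the olfactory genes rose in heterozygous against control heads. Of 11 odorant and gustatory detection genes 3 rose and 0 fell (4 adjusted over the list alone; median 0.45, camera adjusted p = 3.66e-04; adjusted p = 0.231 with an estimated correlation). The olfactory gene Os-C and the odorant-binding protein genes Obp83b and Obp83a rose by 0.94 ± 0.15, 0.93 ± 0.15 and 0.78 ± 0.13 (edgeR adjusted p = 0.00164, 0.00222 and 0.0026). The sugar and lipid metabolism list was called with 2 of 23 genes risen, also when adjusted over the list alone (median 0.22, camera adjusted p = 0.0141; adjusted p = 0.451 with an estimated correlation), and Tps1, trehalose-6-phosphate synthase, rose by 0.69 ± 0.11 (edgeR adjusted p = 0.00204). pst, a learning gene, fell from 236 ± 17.1 to 102 ± 11.2 CPM and Pdf, the clock neuron peptide, rose from 12.2 ± 0.60 to 27.2 ± 5.76 (SD, n = 3; edgeR adjusted p = 2.77e-05 and 0.00404). Lists called close to the threshold were ion channels (1 of 17 fell, 1 adjusted over the list alone; camera adjusted p = 0.0281), odorant-binding proteins (7 rose and 2 fell of 29, 10 and 2 adjusted over the list alone; 0.0436) and heat shock genes (2 of 18 rose, 3 adjusted over the list alone; 0.0436). All 3 had adjusted p = 0.609 with an estimated correlation. The channel list was lost without control replicate 1 or heterozygous replicate 1 (camera adjusted p = 0.127 and 0.0598), the odorant-binding list without control replicate 1 or 2 or heterozygous replicate 3 (0.131, 0.085 and 0.072), and the heat shock list without control replicate 1, heterozygous replicate 2 or 3 or homozygous replicate 2 (0.331, 0.141, 0.103 and 0.0534). The proteasome list (1 of 32 fell, 0 adjusted over the list alone; camera adjusted p = 0.044; adjusted p = 0.745 with an estimated correlation) was lost without control replicate 2 or 3, heterozygous replicate 2 or homozygous replicate 2 (0.129, 0.455, 0.185 and 0.0512). The mushroom body list (2 of 17 fell, 1 up and 2 down adjusted over the list alone; camera adjusted p = 0.044; adjusted p = 0.609 with an estimated correlation) was lost without control replicate 1 or 2, heterozygous replicate 1 or 3 or homozygous replicate 2 (0.297, 0.0783, 0.0527, 0.148 and 0.0512). Correction for exon length also ended 4 of these calls. The medians went from -0.16 to -0.07 for channels, from -0.19 to -0.06 for the mushroom body and from 0.30 to 0.20 for odorant-binding proteins (camera adjusted p = 0.326, 0.242 and 0.242), while the heat shock median barely moved, from 0.64 to 0.61 (0.0658).

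Homozygous flies were compared with heterozygous flies to separate the homozygous state from the effects of 1 mutant chromosome. Ugt35B1 fell again, from 74.1 ± 3.57 to 2.4 ± 0.947 CPM (SD, n = 3; -4.95 ± 0.20, edgeR adjusted p = 5.71e-09). CG31287 fell by 5.34 ± 0.32 (edgeR adjusted p = 6.46e-07), since its reads lay almost all in heterozygous flies. CG31104 (FBgn0051104, 3R 25285473 to 25286974) had 0 reads over the heterozygous and 93 over the homozygous libraries, at least 27.2-fold higher with a floor of 3 reads over the group. CG8757, CG9377 and CG40472 fell by 3.04 ± 0.44, 2.53 ± 0.29 and 2.52 ± 0.23 (edgeR adjusted p = 0.00178, 3.21e-04 and 4.47e-05). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 492 genes were called, 303 higher and 189 lower in homozygous flies, of which 139 and 44 differed at least 2-fold. The libraries did not overlap for 2331 genes, 26.0% against 10% by chance. Without heterozygous replicates 1, 2 and 3 in turn the count was 139, 152 and 172, and without homozygous replicate 3 it was 1099. In the fit without homozygous replicates 1 and 2, which kept 1 homozygous library, many of the 492 calls were lost and others were gained.

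Muscle transcripts that were high in heterozygous heads were lower in homozygous ones. Of 25 muscle genes 2 rose and 8 fell in homozygous against heterozygous flies (2 and 14 adjusted over the list alone; median -0.40, camera adjusted p = 3.58e-06). The muscle genes Mhc, bt and Mlp84B fell by 0.77 ± 0.14, 0.80 ± 0.13 and 0.71 ± 0.12 (edgeR adjusted p = 0.00631, 0.00334 and 0.00565). All 7 lists called here lost their calls with an estimated correlation, 6 of them with adjusted p = 0.524 with an estimated correlation and the odorant detection list with 0.251. Of 10 digestive enzyme genes 9 rose and 0 fell (10 adjusted over the list alone; median 4.82, camera adjusted p = 3.58e-06), with reads again from homozygous replicates 1 and 2 and no call without them (camera adjusted p = 0.318). Neurotransmitter genes fell in 2 of 21 cases, synaptic genes in 2 of 24 and odorant detection genes in 2 of 11 (4, 3 and 6 adjusted over the list alone), with medians of -0.27, -0.21 and -0.47 (camera adjusted p = 5.91e-04 for each). Without homozygous replicates 1 and 2 the first 2 of these lost their calls (camera adjusted p = 0.19 and 0.159). Phototransduction and ion channel genes fell in 2 of 32 and 3 of 17 cases (5 and 4 adjusted over the list alone; camera adjusted p = 0.0248 and 0.0365), calls lost without homozygous replicate 2 (0.0935 and 0.0985), the channel call also without heterozygous replicate 2 (0.0635) and with correction for exon length (0.267). Shab and the potassium channel gene Elk fell by 0.60 ± 0.11 and 0.95 ± 0.17 (edgeR adjusted p = 0.00633 and 0.00565). The odorant detection list was higher in heterozygous than in control heads (median 0.45, camera adjusted p = 3.66e-04). In homozygous against control heads that list was not called (median -0.08, camera adjusted p = 0.877).

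Some genes set homozygous flies apart from both other groups. CCHa2 stood at 39.3 ± 2.63, 26.7 ± 2.36 and 83.5 ± 6.25 CPM in control, heterozygous and homozygous flies (SD, n = 3), and rose in homozygous against heterozygous flies by 1.64 ± 0.13 (edgeR adjusted p = 1.16e-05). Cpr11B stood at 421 ± 71.3, 523 ± 118 and 147 ± 15.7 CPM (SD, n = 3). Ugt35B1 was the one gene among the 10 strongest of this class that fell. The other 9, betaTry, alphaTry, Jon74E, LysD, CG12374, CG18180, CG13323, Muc68E and CG15422, had most of their homozygous reads in replicates 1 and 2. Except for alphaTry, their calls against heterozygous flies were lost without heterozygous replicate 1 and, except for CG15422, also without replicate 2 or 3, with edgeR adjusted p between 0.053 and 0.0907. LysD, betaTry and alphaTry have closely similar neighbours, and reads without a unique position were not counted in genes. In all, 306 genes were called in the same direction against both groups, 201 higher and 105 lower, and 4 in opposite directions. Independent lists of these sizes would share 49.6, and simulated unchanged groups sharing the homozygous libraries gave at most 1. Those simulated groups held no changed genes, so they cannot give the shared calls expected between lists of this length. Because the homozygous libraries serve both comparisons, part of the excess over independent lists may come from them. Without heterozygous replicates 1, 2 and 3 in turn the count was 84, 100 and 111, without homozygous replicate 3 it was 764, and without homozygous replicates 1 and 2 it was 478.

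Many genes differed from control in the same direction in both mutant groups. They included the losses of sordd2, CG8245 and CG31808, the rises of Drsl4, CG34215 and Cyp4p2, and that of BomS2, at 74.7 ± 20.8, 541 ± 220 and 847 ± 134 CPM in control, heterozygous and homozygous flies (SD, n = 3). In all, 564 genes were called the same way in both, 340 higher and 224 lower, and 7 in opposite directions. Independent lists of these sizes would share 83.9, and simulated unchanged groups against the same controls gave at most 0. With no changed genes in them, those simulated groups cannot give the shared calls expected between lists of this length. Across the 8972 genes, which are not independent replicates, the fold changes had Pearson's r = 0.628 (0.518 in simulated unchanged groups) and a covariance of 0.232 (0.0371 simulated, a difference of 0.195). With 3 control libraries the controls could not be split in parts of at least 2, so part of the excess may come from the shared controls. Without each control replicate in turn the count was 365, 295 and 373, without each heterozygous replicate 308, 332 and 275, and without homozygous replicate 3 it was 952.

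Genes near Ime4 were not called more often than others. Within 2 Mb of Ime4 on chromosome arm 3R, 65 of 381 tested genes were called in homozygous against control flies, and 1665 of 8410 elsewhere (Fisher's exact test, odds ratio 0.833, p = 0.21). In heterozygous against control flies 38 of 381 were called (odds ratio 1.08, Fisher's exact p = 0.652) and in homozygous against heterozygous flies 23 of 381 (odds ratio 1.11, Fisher's exact p = 0.645). Within 0.5 Mb 9 of 109 genes were called in homozygous against control flies, fewer than elsewhere (odds ratio 0.364, Fisher's exact p = 0.00148). The 2 Mb test in homozygous against control flies also passed in that direction without control replicate 2 or homozygous replicate 2 (odds ratio 0.687 and 0.713, Fisher's exact p = 0.034 and 0.0435).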

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

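The comparison of reads on the lines outside the gene rows was not a planned test, and no test for a cause was run on it. Reads that overlapped more than 1 gene, and so were counted in none, made up 1.52 ± 0.0822% of the total in homozygous libraries and 1.19 ± 0.0891% in control libraries (SD, n = 3). All 3 homozygous libraries lay above all 3 control libraries, in a part of the data that the comparisons did not use. The total also held reads outside annotated genes, 29.4 ± 2.83% of it in control and 19.1 ± 1.62% in homozygous libraries (SD, n = 3). The higher share of the total did not go with more overlapping reads per read in genes. By that measure all 3 homozygous libraries lay within the range of the control libraries. Overlapping reads in control libraries numbered 56767, 78232 and 71882, beside 2730289, 3449227 and 3182093 reads in genes. In homozygous libraries they numbered 94180, 78609 and 90186, beside 4272550, 3607203 and 4051952.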

How the results depend on the processing

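The fits without libraries that held transcripts of other tissues and with correction for exon length were chosen only after the results were seen. The fits lacking homozygous replicates 1 and 2 kept 1 homozygous library, which was assumed to vary like the other groups. Their counts are totals. In the comparisons of homozygous flies with 1 other group, many calls of the full fit were not among them. The cause was not tested for any change given here unless stated.

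Counts of changed genes are given in the order homozygous against control, heterozygous against control, homozygous against heterozygous, any of the 3 groups, homozygous against both and both against control. A threshold of 0.01 gave 860, 316, 159, 813, 90 and 227, and a fold change of at least 2 gave 535, 305, 183, 101 for homozygous against both and 192 for both against control, lower by construction. With only the 2 groups compared heterozygous against control gave 1370. Without a filter homozygous against heterozygous gave 806 and homozygous against both 498. Without homozygous replicates 1 and 2 heterozygous against control gave 1361, homozygous against heterozygous 802 and homozygous against both 478. Without control replicate 3 as well these were 1357, 1049 and 598. DESeq2 gave 1537, 780, 578, 1750, 337 and 517, and limma-voom 1674, 734, 435, 1634, 258 and 515. Leaving out 1 library gave ranges of 1130 to 2477, 362 to 1442, 139 to 1099, 1192 to 2733, 84 to 764 and 275 to 952, the highest each time without homozygous replicate 3. With the replicate number as a block for pairing the counts were 1664, 777, 451, 1704, 271 and 525.

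Lists called numbered 0, 0 and 0 with an estimated correlation. Homozygous against control gave 6 without homozygous replicates 1 and 2 and 7 without control replicate 3 as well, and homozygous against heterozygous gave 4 with fry and 11 after correction for exon length. That correction ended 9 of 31 list calls and kept 22, and it added the clock, Turandot and hemocyte lists in homozygous against control flies (camera adjusted p = 0.0117, 0.0393 and 0.0393), hemocyte and neuropeptide lists in heterozygous against control flies (0.0234 and 0.0311), and fat body, neuropeptide, respiratory chain, odorant-binding and proteasome lists in homozygous against heterozygous flies (0.0335, 0.0165, 0.0138, 0.03 and 0.0125). Leaving out 1 library gave 10 to 12, 9 to 13 and 6 to 10. In homozygous against control flies the direction of the respiratory chain list reversed without homozygous replicates 1 and 2 (camera adjusted p = 0.804) and without control replicate 3 as well (0.996). The proteasome list did so too (0.882 and 0.323), and the digestive list in the second setting (0.445).

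Mettl3 (Ime4) ranged from -3.16 to -2.81 in homozygous against control, from -0.92 to -0.40 in heterozygous against control and from -2.62 to -2.09 in homozygous against heterozygous flies when 1 library was left out. Without homozygous replicates 1 and 2 the last was -2.82, no longer past the threshold. The odds ratio within 0.5 Mb of Ime4 was 0.364, 0.666 and 0.652 in the 3 comparisons, and the 2 Mb ratio ranged from 0.687 to 0.99, from 0.95 to 1.45 and from 0.851 to 1.43 when 1 library was left out. The X-linked minus autosomal difference ranged from -0.0333 to -0.000882, from -0.069 to -0.028 and from 0.0115 to 0.0513. Of the genes named, those with gut reads reversed in homozygous against control flies in the 2 settings without those libraries: betaTry to -0.56 and -0.75, CG12374 to -3.17 and -3.34, LysD to -1.87 in the first and alphaTry to -0.03 in the second. Against heterozygous flies CG12374 reversed to -1.88 and -1.84 and LysD to -0.92 in the first.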

Other observations

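The tests on a lower neuronal share, on gut reads in homozygous replicates 1 and 2 and on the homozygous libraries acting alike, the simulated ratios, and the ratios without homozygous replicates 1 and 2, were chosen only after the result was seen.

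Further lists were not called by camera in homozygous against control heads, where edgeR called 19.7% of all tested genes. Among these lists 3 of 25 muscle genes rose and 0 fell (3 adjusted over the list alone, camera adjusted p = 0.669). Glial genes rose in 2 and fell in 1 of 14 cases, hemocyte genes in 3 and 1 of 11 and glutathione S-transferase genes in 3 and 1 of 29 (2 and 1, 3 and 1, and 3 and 1 adjusted over the list alone; camera adjusted p = 0.715, 0.196 and 0.188). Sugar and lipid metabolism genes rose in 3 and fell in 1 of 23 cases, oxidative stress genes in 3 and 1 of 15 and odorant-binding protein genes in 7 and 1 of 29 (3 and 1, 4 and 1, and 8 and 1 adjusted over the list alone; camera adjusted p = 0.129, 0.714 and 0.406). Odorant detection genes rose in 2 and fell in 1 of 11 cases, sex-biased head transcripts rose in 2 of 8, tRNA synthetase genes in 1 of 17, heat shock genes in 1 of 18 and eye pigment genes in 2 of 18 (3 and 1 for detection, 2, 1 and 1, and 3 up and 3 down for pigment adjusted over the list alone; camera adjusted p = 0.877, 0.421, 0.714, 0.82 and 0.911). Of the 4 tested histone genes, all variant histones, edgeR called 0 in homozygous against control and 1, higher, in homozygous against heterozygous flies. The testis list had 1 tested member, bol, which fell by 0.62 (edgeR adjusted p = 0.0038).

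Ribosomal protein transcripts were higher and synaptic and channel transcripts lower in homozygous than in control heads. Across genes the log2 fold change had a Spearman correlation of -0.298 with exon length. The ribosomal median was 0.40 after correction for exon length and 0.64 before (camera adjusted p = 8.52e-13 with the preset correlation). This argues against length as the whole cause there, as far as the trend, fitted on genes of no list, holds for these genes. With an estimated correlation, 0.67 between members, the uncorrected list was not called (camera adjusted p = 0.428). For synaptic and channel lists a cause in transcript length stays open. Their medians were -0.13 and -0.16 after correction and -0.28 and -0.27 before (camera adjusted p = 0.0117 and 0.101). Fat body genes rose more than glial genes, by a median of 0.55 (95% bootstrap interval 0.135 to 1.17). For these genes this argues against a lower share of neuronal RNA in which all other cell types rose alike. The interval resamples genes, which are not independent replicates, and does not measure the spread between libraries. Fat body reads summed to 6037, 5325 and 4084 RPM in homozygous replicates 1, 2 and 3 and 2663 to 3249 in control libraries. Glial reads summed to 9244, 7875 and 7828 RPM, and 6654 to 6815 in control libraries. The comparison cannot decide on a lower share of neural tissue as a whole, in which glial transcripts would be diluted with neuronal ones. An effect of Ime4 on these transcripts may remain as a hypothesis.

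Digestive enzyme transcripts were higher in homozygous than in heterozygous libraries. Gut tissue in homozygous replicates 1 and 2 is a candidate explanation: the 9 genes of a second gut list chosen for at most 5 reads over the control and heterozygous libraries had 51 and 60 reads there and 1 read in homozygous replicate 3, none of the 3 being part of that choice. The 5 tested members of that list, of 15 counted, had a median of 0.26 (95% bootstrap interval -0.173 to 0.569). That median cannot decide on gut tissue in the group as a whole. Homozygous replicate 3 held 70.8 RPM of the digestive enzyme list, within the 22.3 to 92.5 of the 6 control and heterozygous libraries. The genotype acting alike in all 3 libraries is argued against, since the list median lay above all 6 others in 2 libraries and not in the other.

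Genes changed at least 4-fold in homozygous against control flies had a median ratio of heterozygous to homozygous log2 fold change of 0.603 (95% bootstrap interval 0.473 to 0.691), and simulated heterozygotes equal to control, with the same shared controls, gave 0.0195 (0.00306 to 0.0377). A graded response to the number of Ime4 copies could account for part of the genes at most: 48 of 135 lay between 0.25 and 0.75, 50 above and 37 below. The median was 0.749 (0.623 to 0.835) for the 39 lower and 0.5 (0.326 to 0.611) for the 96 higher genes. The ratio cannot tell the number of Ime4 copies from other differences that heterozygotes carry in 1 copy. Of the 33 higher genes below 0.25, 23 had over 2-fold more scaled reads in each of homozygous replicates 1 and 2 than in replicate 3. Gut tissue is a candidate in these 2 libraries. Without them the median was 0.491 (0.408 to 0.587), 0.535 for lower and 0.451 for higher genes. That fit kept 1 homozygous library, which also set the genes chosen, and no simulation covered it. Variants on mutant chromosome 3 that act on genes of that chromosome are argued against as the whole cause. The odds ratio for lying there was 0.731 (95% interval 0.502 to 1.05, Fisher's exact p = 0.0953). Where the genes lie cannot decide on variants there that change genes on other chromosomes. Genes called in homozygous against heterozygous flies lay there more often (odds ratio 1.27, Fisher's exact p = 0.011). So did genes apart in heterozygotes from both other groups (odds ratio 1.81, Fisher's exact p = 0.00472). Both results met the prediction set beforehand for variants on chromosome 3. Arm 3R, which carries Ime4, gave 0.894 and 1.37 (Fisher's exact p = 0.329 and 0.185). That check was not part of the prediction, and the explanation stays open for both sets. For genes apart in heterozygotes it would need a chromosome that heterozygotes alone carry, which the labels do not state and which need not differ on 3R only. Other differences between the stocks are untested.

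Other groupings of the libraries gave fewer calls in most cases. Each comparison of 2 groups has 10 splits, too few for a share under 0.05; 1 split, the real one, reached 1765, 836 and 492 genes, and the highest other gave 0 each time. For genes changed among the 3 groups 1 of 100 splits reached 1801, with 682 as the highest other. For genes called in both mutant groups against control 1 of 100 reached 564, with 330 as the highest other. For homozygous flies against both groups 2 of 100 reached 306, the highest other at 337 being a split that kept the 3 controls together as the group set apart. At a share of 0.05 these last 3 counts argue against chance assignment of all 9 libraries to the groups. The splits do not test each group by itself. For homozygous flies against both groups they cannot tell a difference of the homozygous libraries from that of the controls, since setting the controls apart gave more genes.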
